A study of Mus musculus with 2 samples.

How the data were processed

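ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, was carried out on mouse CD8+ T cells, and 2 libraries were deposited with 1 peak list each. Per the labels' protocols, the transposed DNA was purified on columns before library construction. The libraries were grouped by their titles, as control and treatment, with 1 library in each group. Another label field reads "Treatment" for the library titled control and "Combined treatment" for the library titled treatment, so the titles and that field do not name the groups alike, and neither says what was given. Control and treatment below mean the libraries carrying these titles.

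Per the submitters' processing notes, the upstream tools were cutadapt 2.5, Bowtie2 2.3, Picard 2.20 and MACS2 (no version given), and the genome build was mm10. Their settings, any filter on mapping quality or duplicates and any shift of reads for the transposase were not given in the sources used here. The peak lists are in the narrowPeak layout, called per library and not on pooled reads. Each deposited peak carries the authors' score, which equals the −log10 q-value times 10 cut to a whole number in every peak but 1 of the treatment list. It also carries the authors' fold enrichment over local background as a ratio, and the −log10 p-value and −log10 q-value of the authors' peak caller. The lowest deposited −log10 q-value was 2.00 in each library. These values per peak are the authors' own and were used to describe, rank or filter peaks within a list. Between the libraries they were used only for the depth below and for coverage and fold at shared peaks in the closing section.

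Intervals on chromosomes 1 to 19, X and Y were kept. No interval was repeated, so each counted once. A peak was called shared when it overlapped a peak of the other library by at least 1 bp, and single-library otherwise. Percentages carry 95% Wilson intervals, which cover counting error only. With 1 library per group there is no replicate check, no test was made between the groups, and every statement compares these libraries and not the conditions.

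Read numbers were not used here, so depth was taken from the peaks. The fold enrichment and the −log10 p-value of a peak together gave a whole-number read coverage at its summit and the local background, to within 0.001 in −log10 p, for 99.994% of control and 99.977% of treatment peaks. On 20000 simulated peaks the coverage was recovered exactly in 100%. With the −log10 p of each simulated peak raised by a random factor, a whole-number coverage was still found in 0.645%. The lowest background, shared by 33.0% of control and 32.8% of treatment peaks, was 14.2 and 15.0 reads. Divided by the narrowest peak width, 176 and 186 bp, it differed by a ratio of 1.006 between treatment and control. This puts both libraries at about the same total depth if that width is the fragment length and the caller ran alike on both. The share of reads on the chromosomes kept was not known. No other measure of depth was at hand.

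Gene positions came from a RefSeq gene table of the same assembly as mm10, with 21883 protein-coding genes on the chromosomes kept. Of all gene ends, 41.0% held a control peak within 1 kb, against 15.2% after moving every gene by 100 kb. Strand, exons and transcript starts were not used here, so the planned promoter became a gene end, within 1 kb of either end of a gene's span. Peaks were placed by their summit at a gene end, in a gene body or between genes. Sequence was not used here either, so the planned count of 16 motifs was not run.

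A gene's locus was its span with 10 kb on each side, and locus peaks are the peaks touching it. There were 19 gene lists fixed before the data were examined: naive and memory; effector; inhibitory receptors and exhaustion; T cell receptor and CD8 identity; activation and costimulation; migration and residency; interferon response; glycolysis; fatty acid oxidation; cell cycle; markers of B cells, myeloid cells, dendritic cells, CD4 T cells, NK cells, melanocytes, erythroid cells and stromal cells; and neuron and liver genes not expected in T cells. They hold 288 distinct genes, of which 3 stand in 2 lists, and Znf683 and Mx1 found no protein-coding match. For each list, the mean log2 ratio of treatment to control locus peaks, with a pseudocount of 0.5, was placed among 10000 random lists of the same size, matched on the summed locus peaks of both libraries in deciles. A percentile above 97.5 or below 2.5 was taken as standing apart, as a description of these libraries. On simulated data, 100% of 40 lists of kept genes lay above the upper limit, and 8.00% of 200 unchanged lists lay outside the limits, somewhat more than the nominal share. The simulation kept every peak of the kept genes and thinned all others at 1 rate. It had no treatment-only peaks and no dependence of loss on peak strength, so these shares need not hold for the real lists.

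Named genes followed a rule fixed in advance. It took a set of 20 anchor genes, up to 4 members per list with the largest difference in each direction, and the 10 genes over the genome with the largest difference in each direction. It added the 10 strongest single-library peaks per library with no peak of the other library within 1 kb, and the 10 genes per library with the strongest gene-end peak found in that library only. Some of them are not reported here. Alternatives were a −log10 q-value of at least 5 or 10, merging within 100 bp, other definitions of sharing, and gene ends within 2.5 kb. Others were loci of the gene body alone or with 50 kb, and lists of equal length, cut by −log10 p-value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.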

Results

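Chromatin accessibility was profiled by ATAC-seq in mouse CD8+ T cells, which the series title spells Peml-1, with 1 library titled control and 1 titled treatment. The title speaks of a distinct genome-wide chromatin landscape, and the question addressed here is how the accessible regions of these libraries differ. The labels do not say what the treatment was. The control list held 85285 peaks and the treatment list 65098, of which 85137 and 64910 lay on chromosomes 1 to 19, X and Y. There was no replicate of either library, so no difference below has been checked against the spread between replicates.

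The treatment library held fewer accessible regions than the control, and nearly all of those it held were also found in the control. The locus of Il7r, the receptor chain for the survival cytokine IL-7, went the other way, with 9 peaks in treatment and 4 in control. Most of its peaks found in treatment only were weak. The locus of Cd244a, a receptor of the SLAM family found on effector and exhausted CD8+ T cells, had 4 peaks in treatment and 11 in control. Over the genome, the number of peaks in treatment was 0.762 times that in control, and the sequence covered was 41.0 Mb against 53.5 Mb.

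Of the control peaks, 70.8% (95% Wilson interval 70.5 to 71.1%) overlapped a treatment peak, and of the treatment peaks 93.2% (93.0 to 93.4%) overlapped a control peak. This left 24877 peaks in the control library only and 4415 in the treatment library only. Single-library peaks were the weaker ones of their own list. Their median fold enrichment was 4.42 in control, against 10.8 for shared control peaks, and 2.74 in treatment, against 7.91 for shared treatment peaks. Among the control peaks in the highest quartile of fold enrichment 97.4% were shared, and in the lowest quartile 38.3%. The corresponding treatment values were 99.9% and 77.4%. The excess of control-only peaks, 20462, was about the difference in list length, 20227. Nearly equal numbers of shared peaks, 60260 in control and 60495 in treatment, make these values close by construction. With the control list reduced to its 64910 peaks of highest −log10 p-value, 10848 control peaks and 10446 treatment peaks were unshared. Lists of equal length force these numbers to be close.

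**Figure D1:**
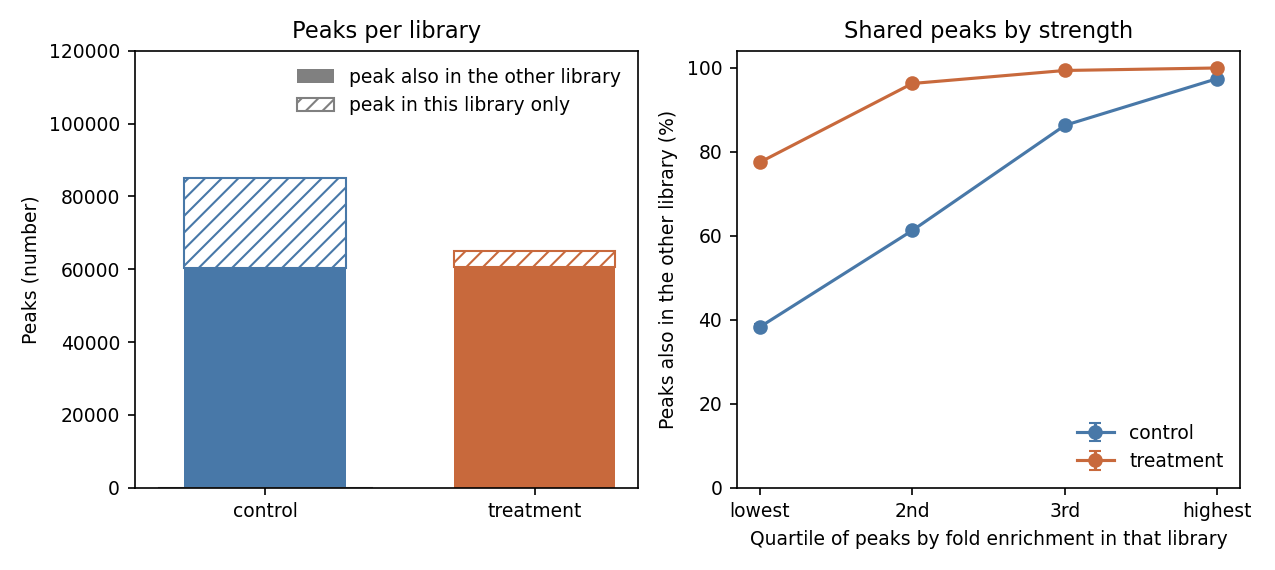
Number of peaks per library, divided into peaks also found in the other library (filled) and peaks of that library only (hatched), and the percentage of shared peaks in each quartile of fold enrichment of that library, with 95% Wilson intervals that are smaller than the symbols. The control bar carries 24877 unshared peaks and the treatment bar 4415, and the shared percentage rises from 38.3% to 97.4% in control and from 77.4% to 99.9% in treatment.

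Shared peaks lay at gene ends far more often than single-library peaks did. Gene ends, within 1 kb of either end of a protein-coding gene, held 21.3% (20.99 to 21.64%) of the shared control peaks, 7.63% (7.30 to 7.96%) of the control-only peaks and 4.598% (4.02 to 5.26%) of the treatment-only peaks. The order of the single-library shares was the opposite with lists of equal length (5.40% of control-only and 7.48% of treatment-only), at 50% reciprocal overlap and with summits within 150 bp. Gene bodies held 44.7% of shared control peaks, 50.8% of control-only and 54.5% of treatment-only peaks. The remaining 34.0%, 41.6% and 40.9% lay between genes. A gene-end peak was present in both libraries at 13399 of 21883 genes, in control only at 1060, in treatment only at 68 and in neither at 7356. With lists of equal length, the gene-end counts were 407 in control only and 356 in treatment only.

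In the 6 lists of T cell state, identity, activation and migration genes, 5 of 122 genes (4.10%) had a gene-end peak in control only, against 4.84% of all genes. This grouping was made after seeing the data and leaves out the CD4, helper and regulatory T cell list, with 3 of 14. The share of all genes includes the 33.6% with no gene-end peak in either library, far more than in the 6 lists, so the bases are unlike. Among the 122 genes, Klrg1, a marker of terminally differentiated effector cells, Egr2, a transcription factor induced by the antigen receptor, and Itga1, an integrin of tissue-resident cells, had a gene-end peak in control only. The strongest control-only gene-end peaks by fold enrichment were at Ms4a4d (23.2), Zkscan2 (20.1), Psd3 (19.8), Lig1 (19.5) and Sema4c (19.3). At Ms4a4d and Lig1 no locus peak was control-only, so the treatment library had an overlapping peak just outside the 1 kb window. The strongest treatment-only gene-end peaks were at Nudcd3 (16.2), Wfdc18 (11.6) and 4931429L15Rik (10.8), and the next, at Mdm4, had a fold enrichment of 3.73. At 4931429L15Rik no locus peak was treatment-only, so there the control library had an overlapping peak just outside the window. Of the genes with a gene-end peak in 1 library only, 1001 in control and 63 in treatment had a peak there without any overlap in the other library.

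The naive and memory genes had nearly as many peaks in treatment as in control. Their 20 loci held 319 peaks in control and 306 in treatment, a ratio of 0.959 against 0.777 for the loci of all protein-coding genes. Of the treatment peaks at these loci, 14.4% (10.9 to 18.8%) were absent from control, against 6.28% over all loci, and of the control peaks 18.2% (14.3 to 22.8%) were absent from treatment, against 27.5%. The latter share was lower at activation (13.8%) and migration loci (15.7%) and about the same at effector loci (19.05%), so it did not set this list apart. The former was the highest of the T cell lists, though myeloid genes (15%) and neuron and liver genes (17.4%) had more. The mean log2 ratio of locus peaks was −0.07, at percentile 99.75 of matched random lists, and 98.8 without Il7r.

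Of the 20 naive and memory genes, 4 had more peaks in treatment, 11 fewer and 5 as many. Il7r (chromosome 15, 9506159 to 9529941) had 9 peaks in treatment and 4 in control, with 6 found in treatment only, of which 5 lay near 1 end of its span, between 9502232 and 9508357. Slamf6, a receptor of progenitor-like CD8+ T cells, had 8 in treatment and 6 in control. Cd28, the main costimulatory receptor, had 9 and 8, and Tcf7, the transcription factor TCF1 of naive and memory cells, had 12 and 11. No Tcf7 locus peak was found in 1 library only, so its extra peak lay where control had a peak too. Peaks in treatment and control numbered 8 and 8 at Ccr7, a chemokine receptor for lymph node entry. The fewer-peak side was led by Bcl2, with 37 and 42, Satb1, with 19 and 23, and Bach2, with 41 and 44. With lists of equal length the sign changed at Bcl2, Satb1 and Bach2, which then had more peaks in treatment, while the percentile of the list was 99.87. With 50 kb on each side Tcf7 had 1 peak fewer in treatment.

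**Figure D2:**
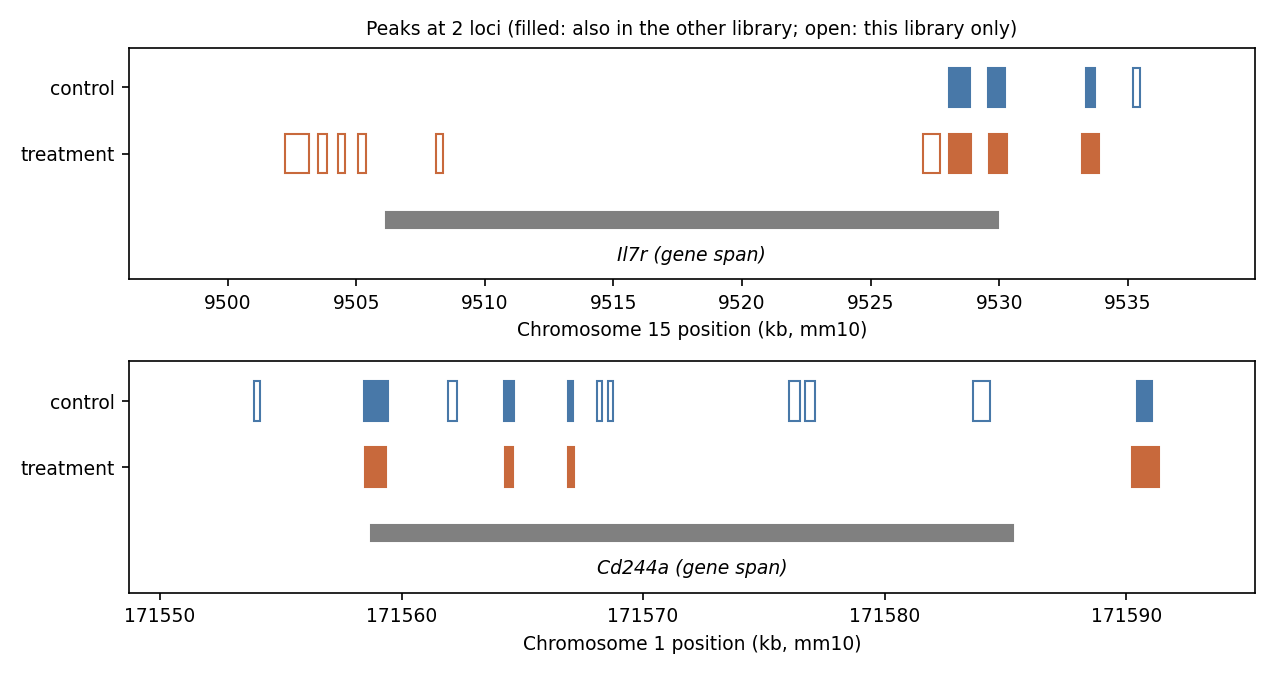
Peaks at the Il7r and Cd244a loci with 10 kb on each side, by position in kb on mm10. Filled boxes are peaks also found in the other library, open boxes are peaks of that library only, and the grey bar is the gene's span; Il7r carries 6 open treatment boxes and 1 open control box, and Cd244a carries 7 open control boxes and no open treatment box.

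The genes of inhibitory receptors and exhaustion had no member with more peaks in treatment. Of the 22, 16 had fewer and 6 as many, with 185 peaks in control and 142 in treatment. Control-only peaks made up 27.0% (21.1 to 33.8%) and treatment-only peaks 2.11% (0.721 to 6.03%). Cd244a (chromosome 1, 171558718 to 171585316) had 7 control-only peaks. Tox2, a relative of the exhaustion regulator Tox, had 7 peaks in treatment and 12 in control. Cd38, an ectoenzyme of dysfunctional T cells, had 2 and 6, and Nfatc1, a factor downstream of calcium signalling, had 20 and 25. Havcr2, the inhibitory receptor TIM-3, had 4 and 7, Tigit 5 and 7, Entpd1 (CD39) 11 and 14, and Tox 15 and 18. Pdcd1, which encodes PD-1, had 6 and 7, and Lag3, Ctla4 and Nr4a1 had as many in each library, 6, 7 and 6. The mean log2 ratio of −0.39 was at percentile 21.03, close to that of other genes with as many peaks, but at 0.92 with lists of equal length, where Nfatc1 and Tox had more peaks in treatment.

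The effector genes had 105 peaks in control and 89 in treatment, with 4 members higher, 13 lower and 7 equal in number, and the list was at percentile 90.2. Prdm1, which encodes the terminal differentiation factor Blimp-1, had 9 peaks in treatment and 13 in control, and Eomes, a T-box factor, had 3 and 6. Gzmb and Prf1, the cytotoxic granule proteins granzyme B and perforin, each had 3 and 5, Klrg1 had 1 and 3, Ifng 5 and 6, Tbx21 5 and 6, and Tnf 7 and 7. Gzma and Id2 had 4 and 3, Fasl 5 and 4, and Gzmf 2 and 1. At Gzma, Fasl and Gzmf every treatment peak overlapped a control peak, and Id2 had 1 treatment-only peak. Treatment-only peaks made up 2.25% (0.618 to 7.83%) at these loci. With lists of equal length Gzmb had more peaks in treatment, and with 50 kb on each side Id2, Fasl and Gzmf had fewer. Gzma had 1 peak fewer in treatment at a coverage of at least 100, a setting chosen after seeing the data.

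T cell receptor and CD8 identity genes had 265 peaks in control and 232 in treatment, at percentile 98.9. Cd5, an inhibitor of receptor signalling, had 11 peaks in treatment and 7 in control, Cd8b1 11 and 9, and Cd3e 8 and 7, while Cd8a had 7 and 9. The 4 treatment-only peaks at Cd5 had summit coverages of only 54 to 82 reads. Fewer peaks were found at Bcl11b (27 and 37), Ptprc (24 and 33) and Runx3 (11 and 16). With lists of equal length Bcl11b, Ptprc and Cd8a had more peaks in treatment, and with 50 kb on each side Cd8b1 and Cd3e had fewer. Migration and residency genes were at percentile 98.7, with 94 and 102 peaks. Itgae, the integrin CD103, had 12 and 10, and Itga1 had 4 and 8. Neither list held under all settings: with gene bodies alone the T cell receptor list was at 95.5 and the migration list at 94.8, with 50 kb at 97.50 and 91.2, and the migration list was at 87.5 with lists of equal length. Both also fell inside the limits with gene length matched (92.0 and 97.0), the former without Cd5 (95.1) and the latter without Cxcr4 (96.5), settings chosen after seeing the data.

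The other functional lists did not stand apart at the main settings. Activation and costimulation genes were at percentile 97.48, with 119 peaks in treatment and 130 in control, and Egr2 and Rel each had 2 and 4. At a −log10 q-value of at least 10 this list was at 99.2, above the limit. Interferon response genes were at 58.1, and Irf9 and Isg20 each had 3 and 5. Glycolysis genes were at 43.1, with Pfkp at 8 and 13 and Slc2a1, the glucose transporter GLUT1, at 6 and 9. Fatty acid oxidation genes were at 71.4, with Cpt1a, the enzyme of fatty acid import into mitochondria, at 8 and 11. Cell cycle genes were at 25.4, with 51 and 71 peaks and 0 of 51 found in treatment only (upper Wilson limit 7.005%). Mki67, the proliferation antigen Ki-67, had 4 and 10, Rrm2 4 and 8, Top2a 2 and 5, and Cdk1 1 and 3. With lists of equal length Mki67, Pfkp, Cpt1a and Irf9 each had 1 peak more in treatment. Of the 19 lists, 3 stood higher and 0 lower than the limits. The nominal share would put 0.95 outside, and the share found on simulated lists 1.52. The simulation was simpler than these data, so neither gives their chance rate.

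**Figure D3:**
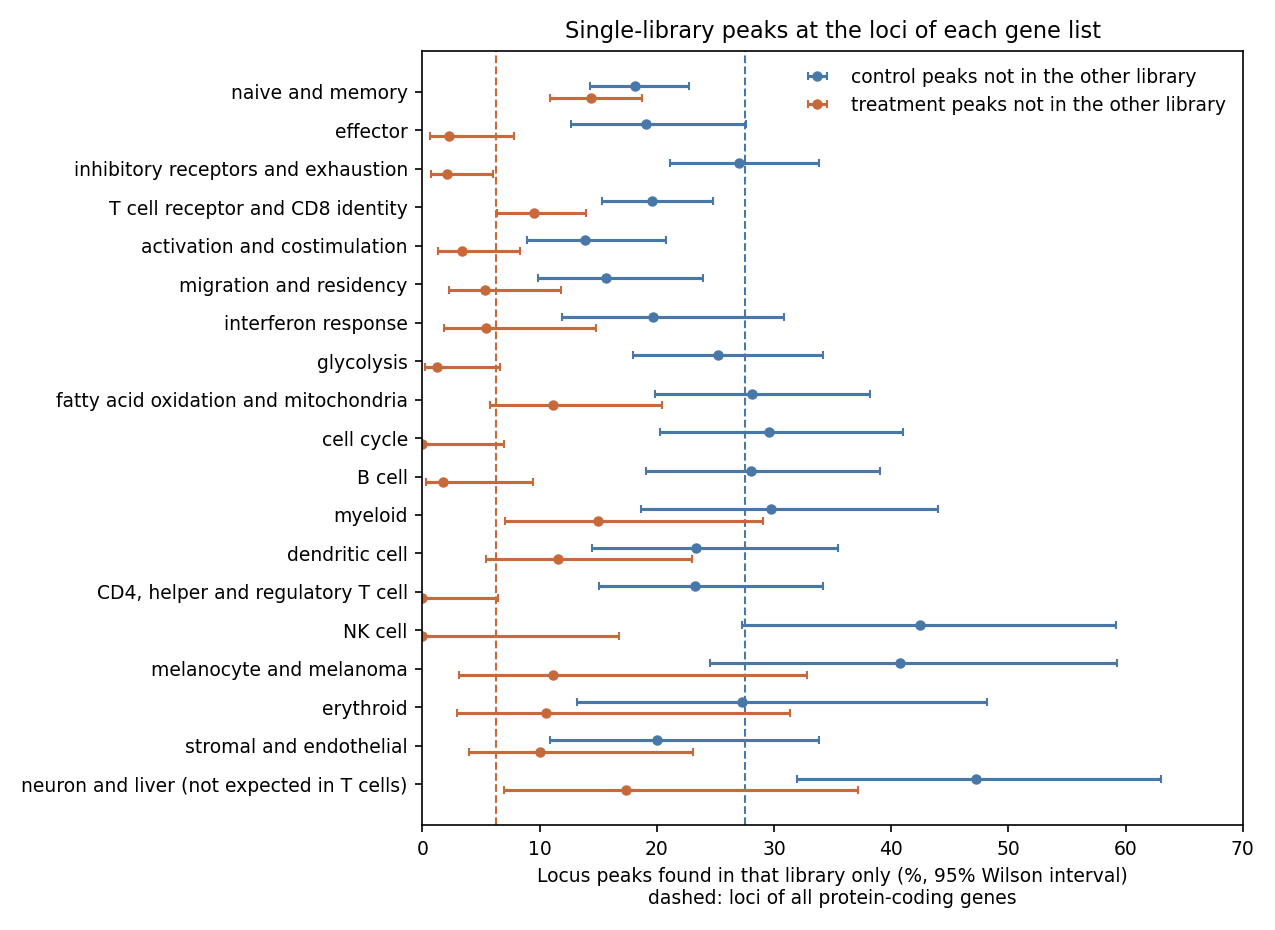
Percentage of the peaks at each gene list's loci found in that library only, for control and treatment peaks, with 95% Wilson intervals; dashed lines mark the loci of all protein-coding genes, 27.5% for control and 6.28% for treatment. The naive and memory list has the lowest gap between its values, 18.2% and 14.4%, and the cell cycle, CD4 T cell and NK cell lists have no treatment-only peak.

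Like all 19 lists, markers of every other cell type had fewer peaks in treatment than in control, as did genes not expected in T cells. The ratio of treatment to control was above the 0.777 of all protein-coding genes at myeloid (0.851), dendritic cell (0.867), erythroid (0.864) and stromal loci (0.889). It was below 0.777 at the other lists of this paragraph. B cell genes had 56 peaks in treatment and 75 in control, at percentile 82.9, and Bank1 had 8 and 14, Fcer2a 3 and 8, and Ms4a1, which encodes CD20, 1 and 0. NK cell genes had 19 and 33 (percentile 9.30), with Klrb1c at 2 and 6, and CD4 T cell genes 56 and 73 (9.11), with Il17f at 0 and 4 and Ikzf2 at 9 and 13. Myeloid genes were at 25.01, where C1qa had 0 and 3 and Spi1 7 and 5. Spi1 had 1 peak fewer in treatment at a summit coverage of at least 100, a setting chosen after seeing the data. Dendritic cell genes were at 31.7, with H2-Aa at 4 and 7 and Flt3, a cytokine receptor of progenitors, at 9 and 6. Melanocyte genes were at 17.2, with Sox10 at 1 and 5 and Pmel itself at 5 and 4, with 1 peak fewer in treatment at a −log10 q-value of at least 5 or 10. Erythroid genes were at 47.3, stromal genes at 70.9, with Pdgfra at 2 and 4, and neuron and liver genes at 49.3, with Rbfox3 at 12 and 20 and Gad1 at 2 and 6. Rbfox3 had more peaks in treatment with lists of equal length.

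Over all genes, 9783 had fewer locus peaks in treatment, 1236 more and 10864 as many, including 4419 with none in either library. The largest deficits in treatment were at long genes: Hivep3 (28 against 53), Arhgap26 (38 against 59), Aopep (23 against 42), Pdzd2 (18 against 36) and Pde4d (28 against 46). Lpp had 30 against 47, Zfp469 11 against 27, Snx29 31 against 47, Inpp4b 73 against 89 and Spata13 21 against 36. Only Inpp4b among these had more peaks in treatment with lists of equal length. The largest excesses in treatment included 5 genes of chromosome 8, among them 4930467E23Rik (16 against 5), Gm5373 (10 against 1), Gm15319 (11 against 2) and 9530057J20Rik (8 against 0). On chromosome 1, Gm38510 had 13 against 5 and Gm7592 17 against 9. Tcp10c had 7 against 0, Gm21119 9 against 2, Zfp978 19 against 12 and Sprr2a2 6 against 0. At a −log10 q-value of at least 10, Gm15319 had 1 peak fewer in treatment than in control, and at a summit coverage of at least 100 reads, a setting chosen after seeing the data, 4930467E23Rik, Gm38510, Gm7592 and Cd5 had fewer as well.

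The strongest control-only peaks with no treatment peak within 1 kb lay mostly between genes. The first, with a fold enrichment of 39.8, was at chromosome 10, 11492078 to 11492260, at 32487 bp from Epm2a, and the next, with 37.2, at chromosome 1, 102628105 to 102628330, was more than 2 Mb from Cntnap5b. Others lay near Ilvbl (28.4), Wnt2 (28.4), Tafa2 (26.2), Zfp41 (25.01), Lyzl1 (24.97) and Inhba (23.995), in the body of Cabcoco1 (24.9), and at 14236 bp from Trat1 (24.98), which encodes a transmembrane adaptor of the T cell receptor. The strongest treatment-only peaks by the folds of their own list lay at chromosome 11, 121982342 to 121982539, near Gm9631 (19.7), in the bodies of Xpo4 (19.5), Nsf (16.5), Nlk (15.95), Supt3 (14.9), Dock4 (14.5) and Fntb (14.3), and near Ms4a4a (15.95) and Enc1 (14.8).

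The ratio of treatment to control peaks ran from 0.724 on chromosome 13 to 0.787 on chromosome 8 among the autosomes. On X it was higher, 0.845, with 1515 and 1792 peaks, and Y had 44 and 50. The share of a library's peaks on a chromosome differed by at most 0.229 percentage points, on X.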

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

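The tests of explanations in this part, the matching on gene length and the comparison of coverage were chosen after the results were seen, while the percentiles of the effector loci, as reported and with lists of equal length, were planned. Peaks on unplaced or unlocalised contigs, which the comparisons left out, numbered 183 in treatment and 141 in control although the treatment list was shorter, 0.281% and 0.165% of the lists, with median folds of 2.82 and 4.42. This is a signal in data no comparison used, above its level in the control library. Mitochondrial peaks numbered 5 and 7.

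The control library had more peaks and more single-library peaks. A lower total depth of the treatment library is argued against by the caller's background per bp of fragment length. Its ratio of treatment to control was 1.006, or 1.063 without division by that length, if the caller ran alike on both libraries. That background does not separate reads on the chromosomes kept from mitochondrial or other reads, so a lower depth of usable reads stays open. A uniform loss of enrichment as the whole cause is argued against by shared peaks compared at equal coverage, where the median log2 ratio at naive and memory loci exceeded that at effector loci by 0.58 (bootstrap interval over genes 0.45 to 0.77). A broad but uneven loss of enrichment in the treatment library was not tested and stays open. Over all shared peaks paired by summits within 150 bp, the median log2 coverage ratio of treatment to control was −0.59. Of these pairs, 10.6% were higher in treatment. The median was negative at gene ends (−0.35), in gene bodies (−0.64) and between genes (−0.69). The treatment itself and a difference in the libraries' preparation cannot be told apart as causes, since there was 1 library per group.

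Naive and memory loci had a higher ratio of treatment to control peaks than matched random lists. Long genes in the list are argued against, between broad classes of length, by the percentile among random lists also matched on these classes, 99.5. Length was not matched within a class, so an effect of length there stays open. B cells in the treatment library as the whole cause are argued against at shared peaks. There B cell loci lay below the naive and memory loci by a coverage-adjusted log2 difference of −0.47 (−0.66 to −0.27). Their own median of −0.16 had an interval, −0.33 to 0.05, that included 0. Shared peaks leave out any B cell peak found in treatment only, so some B cells are not excluded. By peak number the B cell list was at percentile 82.9, and 1 B cell marker, Ms4a1, had a peak in treatment only. A hypothesis of less effector-like beside more naive-like or memory-like chromatin stays open: effector loci were at percentile 90.2 by peak number, but at 78.6 with gene length matched and 23.0 with lists of equal length, never outside the limits, while the coverage-adjusted median at their shared peaks was −0.27 (−0.46 to −0.17). With 1 library per group, the treatment stays untested as a cause of either pattern.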

How the results depend on the processing

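With no replicates, only counting error and these settings limit the values, and depth was compared by 1 measure from the peaks alone. Control had more peaks, more unshared peaks and more genes with a gene-end peak of its own under every setting tried, except that lists of equal length have equal peak numbers and nearly equal numbers of unshared peaks by construction. Shared peaks lay at gene ends more often than unshared ones under every setting, but treatment-only peaks did so more often than control-only ones with lists of equal length, 50% reciprocal overlap and summits within 150 bp, and less often otherwise. The naive and memory list stayed above the upper limit under every setting, from 98.8 without Il7r to 100. Merging within 100 bp moved nothing, since peaks of a list were never closer than 177 bp. The motif counts were not run. The cause of the changes below was not tested unless given.

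At a −log10 q-value of at least 5, 94.3% of treatment peaks were shared. At 10, it was 95.8%, with 2453 treatment-only peaks, 21.9% of shared and 2.77% of treatment-only peaks at gene ends, and 25 treatment-only gene-end genes. With lists of equal length, 83.3% of control and 83.9% of treatment peaks were shared, 10848 and 10446 were not, gene ends held 22.7% of shared, 5.40% of control-only and 7.48% of treatment-only peaks, gene-end genes numbered 407 and 356, and migration and residency fell to percentile 87.5. Of 138 named genes, 22 then had the opposite sign of difference, against 14 with 50 kb. At the stricter q-values or in gene bodies alone, at most 3 did. More genes did not keep their sign when differences that vanished are counted too. These numbered 49 with lists of equal length, 27 with 50 kb and 44 in gene bodies alone. At a −log10 q-value of at least 5 and 10 they numbered 7 and 17.

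At 50% reciprocal overlap, 65.2% and 85.6% were shared, 9368 treatment peaks were not, and gene ends held 22.0% of shared, 8.44% of control-only and 9.30% of treatment-only peaks. With summits within 150 bp, 66.3% and 87.0% were shared, 8445 treatment peaks were not, and gene ends held 9.69% of control-only and 13.7% of treatment-only peaks. Within 1 kb, 74.4% and 94.5% were shared, and gene ends held 20.9% of shared and 7.01% of control-only peaks. Gene ends of 2.5 kb, wider by construction, held 29.0%, 16.2% and 11.6% of shared, control-only and treatment-only peaks.

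For gene bodies alone, T cell receptor and CD8 identity was at percentile 95.5 and migration and residency at 94.8, and with 50 kb at 97.50 and 91.2. The following were chosen after seeing the data. At a recovered coverage of at least 100 reads, 69.5% and 96.7% were shared, and 1503 treatment peaks were not. Gene ends then held 25.2% of shared and 8.62% of control-only peaks, and 23 genes had a treatment-only gene-end peak. At that coverage 9 named genes had the opposite sign. With differences that vanished counted too, 44 did not keep their sign. Matched on gene length too, these lists were at 92.0 and 97.0, without Cd5 the former was at 95.1 and without Cxcr4 the latter at 96.5, with fewer genes. Of the other lists, 124 comparisons stayed inside the limits and 4 left them: inhibitory receptors and exhaustion at 0.92 with equal lists, activation and costimulation at 99.2 with a −log10 q-value of 10 and 99.4 at that coverage, and neuron and liver at 1.65 at that coverage.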

Other observations

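The comparison of coverage in this part was chosen after the peak lists were seen. Read coverage at the summit, recovered from the authors' fold and −log10 p, was set side by side at 56449 pairs of peaks with summits within 150 bp, each divided by its library's lowest background. Such pairs exist only where both libraries had a peak. The median log2 ratio of treatment to control was −0.59, and 10.6% of the pairs were higher in treatment. It was −0.35 at gene ends, −0.64 in gene bodies and −0.69 between genes. This order depended on coverage. From the lowest to the highest quartile of mean coverage, the medians at gene ends were −0.93, −0.95, −0.65 and −0.23. Elsewhere they were −0.69, −0.79, −0.66 and −0.40. A clearly smaller loss at gene ends was thus seen only in the highest quartile, which held 7360 of the 11965 gene-end pairs. At the Il7r locus, the shared peak at chromosome 15, 9533218 to 9533898, had a coverage of 1103 reads in treatment and 154 in control, and the other shared peaks had 649 against 476 and 836 against 503. The authors' fold over local background at the latter peaks went the other way, 4.55 against 9.35 and 4.65 against 9.08, and at the former it was 8.17 against 3.99. At Cd244a, the shared peaks had 117 against 388, 330 against 516, 211 against 284 and 53 against 36, with a median log2 ratio of −0.63, close to that of all pairs. The authors' fold at these peaks was 6.27 against 8.69, 11.4 against 9.79, 7.93 against 6.25 and 3.36 against 2.44. It was thus lower in treatment at the first peak and higher at the others.

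Before any adjustment, the median was −0.20 at naive and memory loci, with 30% of the pairs higher in treatment, −0.44 at T cell receptor and CD8 identity loci and −0.86 at effector loci. With the median at equal mean coverage removed, so that values are relative to other peaks and not gains, the naive and memory loci had a median log2 ratio of 0.31 (bootstrap interval over genes 0.25 to 0.36, 240 pairs), and the T cell receptor and CD8 identity loci 0.13 (0.04 to 0.26). Among genes with 3 or more pairs, Il7r had a median of 1.11, Cd8b1 0.98, Ets1 0.54, Tcf7 0.52 and Bcl2 0.46. Below 0 lay Ltb (−0.18), Id3 (−0.11) and Bcl6 (−0.05) of the former list. Of the latter list, Zap70 (−0.20), Cd5 (−0.20), Thy1 (−0.09) and Lck (−0.07), among others, lay below 0. Unadjusted, Il7r was at 0.64 and Cd8b1 at 0.33, while Ets1, Tcf7 and Bcl2 were at −0.06, −0.10 and −0.12. Adjusted, Cd40lg, the ligand by which helper T cells act on B cells, had 1.45, and Flt3 0.99. Their lists did not follow. The CD4, helper and regulatory T cell loci were at 0.009 (−0.25 to 0.23) and the dendritic cell loci at −0.06 (−0.19 to 0.09). Below 0 with their whole interval lay the effector loci, NK cell loci at −0.47, cell cycle at −0.12, neuron and liver genes at −0.33 and, narrowly, glycolysis at −0.12 (−0.24 to −0.005). The glycolysis interval lay below 0 from only 10 of 20 other seeds of the bootstrap, and the other 4 from all 20. Since genes not expected in T cells are among these, a value below 0 is not particular to effector genes. The neighbouring chemokine genes Ccl3 and Ccl4, whose loci share peaks, had −1.22 and −0.87, Hk2, a glycolytic enzyme, −0.999, and Ifng −0.61. Going the other way in the effector list were Klrd1 at 0.43, Klrk1 at 0.25 and Zeb2 at 0.08. Gzma, Fasl and Id2, which had more locus peaks in treatment, were at −0.74, −0.62 and −0.32. Unadjusted, they were at −1.59, −1.13 and −0.87, with 0 pairs higher in treatment. These genes were chosen after their values were seen. The inhibitory receptor and exhaustion loci were at −0.01 (−0.09 to 0.07). These medians count a pair at each locus it touches. With each pair counted once and genes that share a pair drawn together, the effector loci were at −0.27 (−0.46 to −0.17, 80 pairs), the T cell receptor and CD8 identity loci at 0.13 (0.02 to 0.25), and naive and memory minus effector at 0.58 (0.47 to 0.77).

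Treatment-only peaks formed 36 bins of 100 kb with 5 or more of them, and control-only peaks 1035. Of the treatment bins, 10 lay on chromosome 8 (15 treatment-only peaks in the bin of Gm15319 and 13 in that of 4930467E23Rik), 5 on chromosome 7, 4 on chromosome 4, with 11 peaks in the bin of Zfp982, and the others on 10 further chromosomes. Among these were the bins of the Sprr2a genes (12), Tcp10c (10), Il7r (6) and Ripor2 (6), named after their values were seen. The bin of the Ugt1a genes held 11 treatment-only peaks but also 6 control-only peaks, and 2 of the 36 were bins of both kinds. How reads that match several copies were placed was not given in the sources used here.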
